A study of Homo sapiens with 18 samples.

How the data were processed

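The values analysed were the submitters' gene-level TPM (transcript abundance scaled to a fixed total per library), as deposited in 2 tables that were normalized separately. Per the submitters' processing notes, reads were aligned with HISAT2 to the human genome GRCh37 (hg19) and TPM values were made with StringTie. The versions of both tools are not given in the sources used here. The labels describe total RNA, Nextera XT libraries and paired-end 100-bp sequencing on a NovaSeq instrument. They do not state how human cells were separated from mouse cells after transplantation, how mouse reads were handled, or whether cells from the fibres were sorted. Genes were matched by symbol, and no coordinates were used.

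The transplant table had 26490 rows for 26488 gene symbols, and the 2 symbols on 2 rows were summed. The culture table had 35993 symbols, of which 9505 were not in the transplant table. Those symbols took up 70302 to 121391 TPM of each culture library, so levels were not compared between the tables. Genes with at least 1 TPM in at least 3 libraries of a fit were tested, 14194 in the transplant table and 17146 in the culture table.

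Tests were made in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a trend) on log2(TPM + 1), with group as the only factor. The transplant comparison was fitted on its 6 libraries, and the 5 culture comparisons shared their spread over the 12 culture libraries. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05 and a log2 change of at least 1, which is 2-fold.

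For 23 gene lists, fixed in advance, limma camera was run with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison, with fry beside it. The lists covered the distal tip progenitor, alveolar type 2, alveolar type 1, alveolar transitional (KRT8-high), airway secretory, multiciliated, basal, neuroendocrine, proliferation, non-lung endoderm, pluripotency, mesenchymal, endothelial, and macrophage and leukocyte markers. The others were MHC class II, MHC class I and interferon response, sterol and fatty acid synthesis, glycolysis and hypoxia response, WNT targets, NOTCH pathway, glucocorticoid response, immediate early and dissociation stress, and epithelial fluid transport.

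Named genes followed a rule. Among called genes with a mean of at least 5 TPM in the higher group and no overlap between libraries, the 8 largest changes in each direction were eligible, leaving out ribosomal protein, mitochondrial, pseudogene, antisense, clone-named and small RNA symbols. Up to 4 called members per list described were eligible, with members at 5 TPM or more that were not called where a contrast was described. NKX2-1, CPM, SOX9, SOX2, SFTPC, SFTPB, ABCA3, AGER, PDPN, SCGB3A2, SCGB1A1, FOXJ1, TP63 and MKI67 were always eligible. Some eligible genes are not reported here.

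The comparisons, their tests, the lists, the rule for named genes and the alternatives were chosen before the data were examined, except for alternatives named as added and for the tests and genes stated to have been chosen after the result was seen. Pairing by replicate number was not stated in the labels and came from the data. After group means were removed, replicates of the same number correlated at 0.344, 0.199 and 0.115 between alveolar-differentiated cells and fibre-expanded progenitors, the only 1 of the 6 comparisons where all 3 correlations were above 0.1. A fit with the replicate number as a block was run as an alternative for every comparison.

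In simulated data with the spread of the real libraries and 50 changed genes for each size of change, the transplant comparison recovered 0%, 6%, 34% and 64% of genes at true log2 changes of 1.5, 2, 3 and 4, with 4 false calls among 14194 genes. The culture comparisons recovered 54% to 66% at 1.5 and 94% to 100% at 3, with 5 to 13 false calls among 17146 genes. Changed genes were drawn from those with a mean log2 level of at least 2 and were a small share of all genes. In the real transplant comparison 22.2% of genes were called, and the adjustment is stricter with fewer true changes, so real recovery may differ. Genes were simulated independently with the same SD in every group, without shifts of a whole library, so false calls may be understated.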

Results

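RNA was sequenced from human 201B7 cells, an induced pluripotent stem (iPS) cell line, after they had been turned into lung progenitors, in 18 libraries that fell into 6 groups of 3. The first table held progenitors named mB2-3 and engrafted cells, human cells collected from mouse lung 8 weeks after transplantation. The other table held progenitors named B2-3, progenitors expanded for 4 weeks as a 3D culture inside alginate fibres, and expanded cells that were then differentiated for 2 more weeks towards alveolar or airway epithelium. The values were TPM, transcript abundance scaled to a fixed total per library, a unit that keeps no sequencing depth, so the depth of each library is unknown. Libraries of the transplant table summed to 798199 to 974351 TPM and listed 10393 to 14200 genes at 1 TPM or more. Engrafted replicate 2 had the lowest values of both, 798199 TPM and 10393 genes, and listed 151 genes at 0 that stood at 10 TPM or more in the other 5 libraries of its table. Culture libraries summed to 998773 to 999421 TPM with 13540 to 16015 genes at 1 TPM or more. The replicates carried numbers only, with nothing to say that they came from separate cultures or animals, so the p-values measure the spread between these samples, technical or biological.

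Changes below are differences of log2(TPM + 1) ± standard error (SE) between groups of 3 libraries, a scale that understates changes of genes near 0 TPM. A gene was called changed at a limma adjusted p under 0.05 with a change of at least 1, and TPM levels are means ± SD (n = 3) unless each library is given. For 23 gene lists fixed before the data were examined, the members called are given with the camera test at a preset correlation of 0.01. Where a count of called members is given without a count adjusted over the list alone, both counts were the same. Of 138 list tests, 79 were called at the preset correlation and 10 with an estimated correlation. Those 10 were the airway secretory and multiciliated lists in engrafted cells, the non-lung endoderm, airway secretory and macrophage and leukocyte lists in fibre-expanded progenitors, and the distal tip progenitor and non-lung endoderm lists in airway-differentiated cells. The last 3 were the non-lung endoderm list between the differentiated groups, and the airway secretory and non-lung endoderm lists in alveolar-differentiated cells against B2-3 progenitors. The median, the mean and the test of a list differed in direction only in lists that were not called. These were the neuroendocrine and MHC class II lists in engrafted cells, the mesenchymal list in fibre-expanded progenitors, the pluripotency and NOTCH pathway lists after alveolar differentiation and the immediate early and fluid transport lists after airway differentiation. Between the differentiated groups they were the transitional, basal, endothelial, sterol and glucocorticoid lists, and over the whole culture course the multiciliated and glycolysis lists. Because only 10 of the 79 held with an estimated correlation, a list call at the preset correlation is weak evidence beside its member count. Other splits of the same libraries gave as many list calls as the real one in 4 of the 6 comparisons. Those splits keep part of the group difference, so their counts give no rate of false list calls. In engrafted cells the alveolar type 1, alveolar type 2 and distal tip progenitor lists passed fry (fry adjusted p = 0.00200, 0.00760 and 0.00155). The transitional, glucocorticoid response, immediate early, sterol and fluid transport lists, called at the preset correlation, did not (fry adjusted p = 0.0538, 0.0538, 0.0745, 0.0745 and 0.220). Other fry results are not reported here.

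The first comparison asked what differed between progenitors and the cells that had spent 8 weeks in mouse lung. Engrafted cells carried both airway and alveolar transcripts. SCGB3A2, a secretoglobin of airway secretory cells, was higher by 12.88 ± 0.51 (limma adjusted p = 9.90e-05), at 56798, 66639 and 26936 TPM in the engrafted libraries against 2.89, 5.08 and 9.03 in mB2-3 progenitors, and was the gene with the highest TPM in all 3 engrafted libraries. SFTPC, the surfactant protein of alveolar type 2 cells, rose by 7.31 ± 0.45 (limma adjusted p = 0.000430) to 194, 127 and 184 TPM. SNTN, a protein of the ciliary tip, rose by 7.32 ± 0.66. CAV1, a member of the alveolar type 1 list that codes for caveolin-1 and is not limited to those cells, rose by 6.57 ± 0.47.

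The airway secretory list had 10 of 13 tested members higher and 0 lower (11 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 2.03e-18, and adjusted p = 0.0386 with an estimated correlation). CYP2F1, a lung cytochrome P450, rose by 9.07 ± 0.52. SCGB1A1 stood at 378, 2563 and 1112 TPM and SLPI, an antiprotease, at 2302, 3827 and 834 TPM in engrafted libraries, and both were listed at 0 in all 3 progenitor libraries. Of the multiciliated list 14 of 20 members rose (limma camera adjusted p = 3.65e-18, and adjusted p = 0.0368 with an estimated correlation), among them the axonemal genes RSPH1 (6.85 ± 0.56) and SPAG6 (6.33 ± 0.46). FOXJ1, the regulator of motile cilia, did not pass (1.11 ± 1.18), at 62.6, 1.04 and 26.6 TPM against 4.95, 8.27 and 5.46, and was called without engrafted replicate 2 (2.56, limma adjusted p = 0.00686).

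Surfactant genes of the alveolar type 2 list rose with 9 of 18 members higher (10 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 8.53e-10, and adjusted p = 0.166 with an estimated correlation). SFTPB rose by 9.98 ± 1.18 and SFTPA2 by 10.07 ± 0.90, while ABCA3, the lipid transporter of lamellar bodies, stood at 14.4, 0.192 and 17.9 TPM against 7.44, 5.68 and 5.20 (-0.00 ± 1.03). Without engrafted replicate 2 the change of ABCA3 was 1.28 (limma adjusted p = 0.0360). SFTPA1 and SFTPA2 are near-identical genes whose reads can be split between them, so the level of each is uncertain. In the alveolar type 1 list 11 of 16 members rose (12 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 4.66e-11, and adjusted p = 0.151 with an estimated correlation), including the chloride channel family genes CLIC3 (8.94 ± 0.48) and CLIC5 (5.46 ± 0.56) and the envelope protein gene SCEL (6.63 ± 0.52). PDPN did not pass, at 36.0, 6.57 and 37.0 TPM against 49.0, 52.5 and 38.8. Many genes of this list are also expressed by airway basal and other epithelial cells, and the list also rose in airway-differentiated cells. The alveolar transitional (KRT8-high) list had 5 of 12 members higher (6 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 4.18e-07, and adjusted p = 0.251 with an estimated correlation), and the basal list 3 of 6 higher and 1 lower (limma camera adjusted p = 0.00281, and adjusted p = 0.151 with an estimated correlation). The basal keratins KRT17 and KRT15 rose by 9.63 ± 0.78 and 6.19 ± 0.51, whereas TP63, the basal cell regulator, stood at 1.77, 0 and 1.10 TPM against 1.46, 2.22 and 8.54. Outside the lists, the uroplakin gene UPK2 (9.84 ± 0.39) and the tetraspanin gene TSPAN1 (9.57 ± 0.46) were among the 8 highest changes.

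Progenitor genes were lower. The distal tip progenitor list had 10 of 16 members lower (limma camera adjusted p = 0.000579, and adjusted p = 0.151 with an estimated correlation). SHH, the morphogen of the lung bud, fell by 5.34 ± 0.55 (limma adjusted p = 0.00125). HMGA2 and LIN28B were listed at 0 in every engrafted library, against 52.3, 18.5 and 57.0 and 13.5, 5.69 and 14.7 TPM in progenitors. NKX2-1, the lung lineage regulator, was lower at 151, 26.4 and 117 TPM against 380.4, 319 and 400.0 (limma adjusted p = 0.0473). Its call was lost without mB2-3 replicate 1, 2 or 3 or engrafted replicate 3 (limma adjusted p = 0.174, 0.144, 0.176 and 0.0557), with a range of 0.00652 to 0.176 over all settings. Carboxypeptidase M gene CPM was at 253, 107 and 488 TPM against 413, 432 and 557 and did not pass. Of WNT targets 7 of 11 were lower (0 higher and 10 lower adjusted over the list alone, limma camera adjusted p = 0.00184, and adjusted p = 0.269 with an estimated correlation), with LEF1 and LGR5 listed at 0 in engrafted libraries and SP5 down at -4.19 ± 0.67. The proliferation list had 12 of 26 members lower (0 higher and 19 lower adjusted over the list alone, limma camera adjusted p = 0.000861, and adjusted p = 0.424 with an estimated correlation), but MKI67 did not pass, at 3.44, 0.0216 and 10.4 TPM against 26.9, 8.94 and 14.6.

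Of the non-lung endoderm list, markers of intestine and liver, 7 of 11 members were lower (0 higher and 9 lower adjusted over the list alone, limma camera adjusted p = 0.0187, and adjusted p = 0.399 with an estimated correlation). AFP stood at 29.5, 581 and 41.2 TPM and CDH17 at 8.99, 65.3 and 17.6 TPM in progenitors and both were listed at 0 in all engrafted libraries. That call was lost without mB2-3 replicate 1 or 3 (limma camera adjusted p = 0.192 and 0.233). All 5 tested pluripotency genes were lower (limma camera adjusted p = 0.00717, and adjusted p = 0.251 with an estimated correlation), with LIN28A at 33.2, 9.23 and 5.79 TPM in progenitors and listed at 0 in engrafted cells. Without mB2-3 replicate 1, 2 or 3 the pluripotency list was not called (limma camera adjusted p = 0.0710, 0.0545 and 0.0632). Glycolysis and hypoxia response genes were lower in 9 and higher in 1 of 15 (1 higher and 10 lower adjusted over the list alone, limma camera adjusted p = 0.0115, and adjusted p = 0.346 with an estimated correlation). PDK1, a brake on pyruvate use in mitochondria, changed by -3.52 ± 0.51, ADM by -3.19 ± 0.40 and P4HA1 by -3.09 ± 0.42. Sterol and fatty acid synthesis genes were lower in 7 of 17 (0 higher and 9 lower adjusted over the list alone, limma camera adjusted p = 0.0189, and adjusted p = 0.568 with an estimated correlation). The desaturase FADS1 changed by -3.86 ± 0.60, and the list was not called without engrafted replicate 1 (limma camera adjusted p = 0.0538).

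MHC class I and interferon response genes were higher in 6 of 15 (8 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 1.79e-08, and adjusted p = 0.166 with an estimated correlation), including IFIT3 (4.14 ± 0.62) and the immunoproteasome gene PSMB8 (4.04 ± 0.47). The immediate early and dissociation stress list, which moves with tissue handling, had 4 of 13 members higher (5 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 4.18e-07, and adjusted p = 0.251 with an estimated correlation). ZFP36, which destabilizes cytokine mRNA, rose by 4.71 ± 0.58. The mean log2 level of that list was 9.26, 7.20 and 9.02 in engrafted libraries against 6.34, 7.49 and 6.40 in progenitors, with engrafted replicate 2 below progenitor replicate 2. Glucocorticoid response genes were higher in 4 and lower in 1 of 10 (limma camera adjusted p = 0.00408, and adjusted p = 0.251 with an estimated correlation). The kinase gene SGK1 rose by 3.33 ± 0.46 and NFKBIA, the inhibitor of NF-kB, by 2.85 ± 0.33. The lower member was FKBP5, and 5 members were not called. Epithelial fluid transport genes were higher in 2 and lower in 1 of 10 (limma camera adjusted p = 0.00164, and adjusted p = 0.358 with an estimated correlation). The water channel AQP4 rose by 5.15 ± 0.64. Lists of other lung cells did not pass. Mesenchymal genes were lower in 3 of 6 (limma camera adjusted p = 0.0655). The collagen gene COL1A2 changed by -4.56 ± 0.51, and EGFL7, the only 1 of 12 endothelial genes to pass the filter on TPM, was at -5.02 ± 0.56 (limma camera adjusted p = 0.0782), which does not stand for the list. Macrophage and leukocyte genes were higher in 2 and lower in 1 of 3 (limma camera adjusted p = 0.0536). CTSS, a lysosomal protease gene, rose by 3.63 ± 0.43. NOTCH pathway, MHC class II and neuroendocrine lists had 1 of 10, 1 of 7 and 1 of 6 members lower, and 1 MHC class II gene was higher (limma camera adjusted p = 0.462, 0.870 and 0.713). Adjusted over the list alone, the MHC class II list had 1 higher and 2 lower and the neuroendocrine list 0 and 0.

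In all, 3145 of 14194 genes were called in engrafted cells against mB2-3 progenitors, 909 higher and 2236 lower, and the libraries of the groups did not overlap in 50.6% of all tested genes, where chance gives 10%. The median change of all tested genes was -0.84, and the genes that fell most were COL2A1 (-7.89 ± 0.63), CPXM1 (-7.89 ± 0.49) and CDH2 (-7.53 ± 0.68). Median-of-ratios scaling gave 1205 higher and 1310 lower genes, and quantile normalization 1404 and 1240. Without mB2-3 replicate 1, 2 or 3 the count fell to 471, 608 or 527, with more genes higher than lower in each (322 and 149, 389 and 219, and 351 and 176). The median change of all genes in those refits was -0.79, -0.80 and -0.74, so the shift stayed while most calls were lost. With fewer libraries of a group the filter of 3 libraries also drops genes near 0 in the other group, so part of these splits is set by the filter. Without engrafted replicate 1 or 3 there were 352 higher and 1778 lower, or 465 and 2024.

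**Figure D1:**
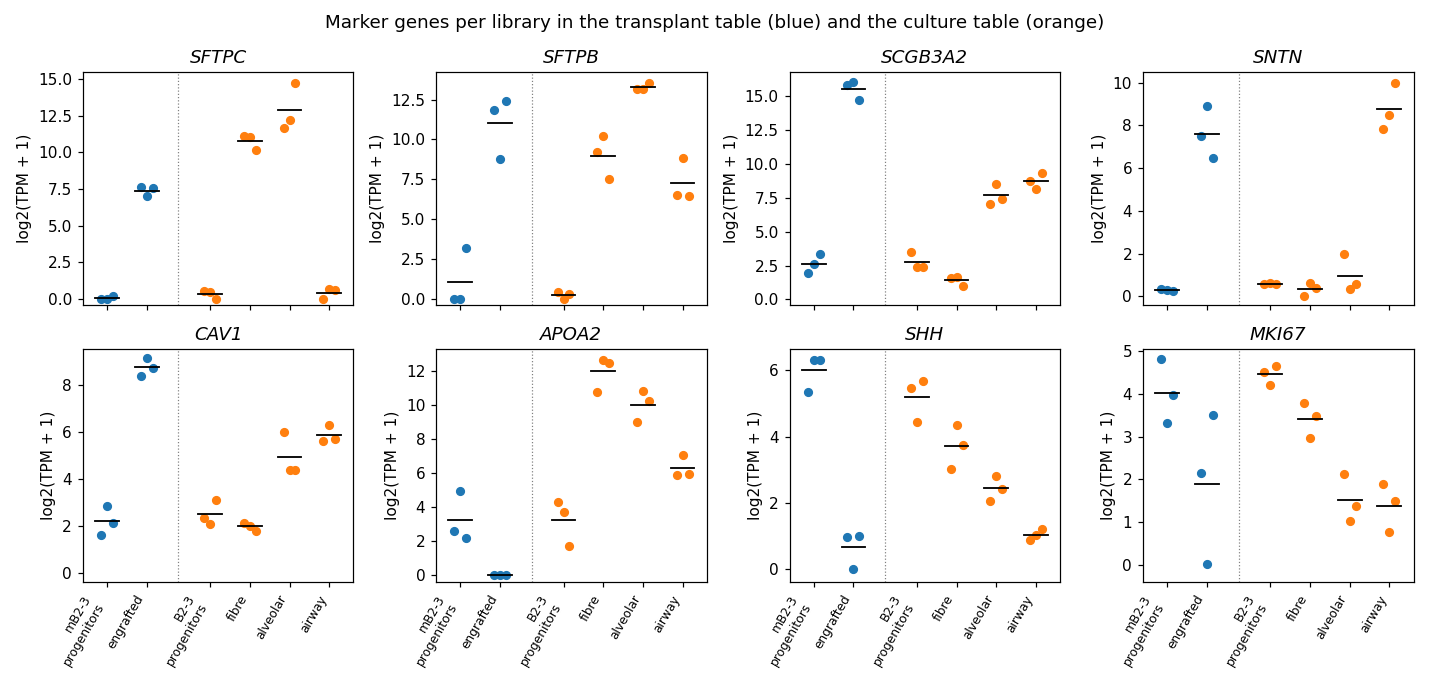
Each point is 1 library and each black bar the mean of 3 libraries, on a log2(TPM + 1) axis, for 8 genes in the 2 groups of the transplant table (blue) and the 4 groups of the culture table (orange), which were normalized separately. SFTPC was near 0 in mB2-3 and B2-3 progenitors and in airway-differentiated cells, but not in fibre-expanded progenitors, and SNTN was high in engrafted and airway-differentiated cells.

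Expansion in alginate fibres was compared with the starting B2-3 progenitors. Fibre-expanded progenitors gained surfactant transcripts and, together with them, transcripts of gut and liver. SFTPC rose by 10.45 ± 0.60 (limma adjusted p = 3.86e-07), from 0.267 ± 0.234 to 1832 ± 619 TPM, and SFTPB by 8.75 ± 0.64. FABP1, a fatty acid binding protein of liver and intestine, rose by 7.91 ± 0.40 (limma adjusted p = 1.22e-07), and APOA2, a liver apolipoprotein, by 8.71 ± 0.67.

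The alveolar type 2 list had 11 of 20 members higher and 0 lower (13 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 1.85e-11, and adjusted p = 0.133 with an estimated correlation). SFTPA1 rose by 9.81 ± 0.76. Alveolar type 1 genes went the other way in 6 and rose in 1 of 18 (2 higher and 6 lower adjusted over the list alone, limma camera adjusted p = 0.184). PDPN, which codes for podoplanin, changed by -3.45 ± 0.50, HOPX by -2.40 ± 0.51, COL4A3 by -2.94 ± 0.50 and TNNC1 by -2.89 ± 0.55. The non-lung endoderm list had 12 of 15 members higher and 0 lower (limma camera adjusted p = 9.78e-16, and adjusted p = 0.00200 with an estimated correlation), including LGALS4 (8.13 ± 0.57) and the gastric peptide TFF1 (7.26 ± 0.94). The intestinal genes CLCA1, REG4 and APOA4, at 1820.1, 2687 and 1081, 824, 849 and 528 and 174, 762 and 880.4 TPM in the fibre libraries, were listed at 0 in every B2-3 library. LYZ, which codes for lysozyme, rose by 10.73 ± 0.77. Airway secretory genes were higher in 5 and lower in 1 of 12 (6 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 1.06e-05, and adjusted p = 0.0434 with an estimated correlation), led by AGR2 (8.09 ± 0.40). The other higher members were TFF3, SPDEF, PIGR and MSMB, and the 1 lower member was the secretoglobin SCGB3A2. Of the neuroendocrine list 7 of 13 members rose (8 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 1.49e-07, and adjusted p = 0.141 with an estimated correlation). The granule protein genes CHGA and SCGN rose by 7.28 ± 0.58 and 3.74 ± 0.39.

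Fibre-expanded cells also had 10 of 15 MHC class I and interferon response genes higher (10 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 1.45e-07, and adjusted p = 0.133 with an estimated correlation). OAS1, an antiviral RNA sensor, rose by 6.28 ± 0.40. BST2, an interferon-induced antiviral gene outside that list, fell by 4.91 ± 0.63. Macrophage and leukocyte genes were higher in 3 of 4 (limma camera adjusted p = 0.000329, and adjusted p = 0.0434 with an estimated correlation), with the lysosomal genes CD68 (5.29 ± 0.49) and CTSS (2.43 ± 0.43), both also expressed outside leukocytes. The macrophage receptor gene CSF1R stood at 4.94, 0.311 and 2.53 TPM against 0.0352, 0.188 and 0.255 (1.38 ± 0.45, limma adjusted p = 0.0497), a call lost without B2-3 replicate 1, 2 or 3, alveolar replicate 2 or 3 or airway replicate 1, 2 or 3 (range 0.00412 to 0.132 over all settings). Transitional genes rose in 3 of 12 (limma camera adjusted p = 0.000868, and adjusted p = 0.305 with an estimated correlation). LGALS3 rose by 3.93 ± 0.24 and the cell cycle inhibitor CDKN1A by 2.80 ± 0.37. Epithelial fluid transport genes rose in 4 of 10 (limma camera adjusted p = 0.000969, and adjusted p = 0.168 with an estimated correlation). The tight junction gene CLDN18 rose by 5.12 ± 0.52 and the water channel AQP3 by 3.78 ± 0.35. The sterol and fatty acid synthesis list was called higher with 1 of 17 members called (limma camera adjusted p = 0.000969, and adjusted p = 0.538 with an estimated correlation).

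The distal tip progenitor list moved both ways, with 2 of 16 members higher and 4 lower (3 higher and 6 lower adjusted over the list alone, limma camera adjusted p = 0.559). The FGF target genes ETV5 and ETV4 rose by 3.03 ± 0.43 and 3.00 ± 0.45, and MYCN fell by 3.20 ± 0.48. NKX2-1 was at 134 ± 16.4 TPM against 261 ± 34.4, a change of -0.96 ± 0.27 that was under the limit of 1 and passed it without B2-3 replicate 2 (-1.06) or fibre replicate 1 (-1.05). CPM was at 252 ± 35.5 against 443 ± 32.8 TPM, and SOX9 at 37.2 ± 17.1 against 20.8 ± 6.60 TPM. Proliferation genes were lower in 4 of 26 (limma camera adjusted p = 0.296), with MKI67 at 9.95 ± 3.00 against 21.0 ± 3.41 TPM. CCN1 and CCN2, targets of YAP signalling, were lower (-5.09 ± 0.69 and -5.52 ± 0.98), as were the WNT ligand WNT11 (-4.45 ± 0.51) and ADM (-4.24 ± 0.54), the gene of the vasodilator peptide adrenomedullin. Immediate early and dissociation stress genes were lower in 6 of 13 (0 higher and 8 lower adjusted over the list alone, limma camera adjusted p = 0.0206, and adjusted p = 0.725 with an estimated correlation). DUSP1, a phosphatase gene of the early stress response, changed by -4.02 ± 0.80, and the list call was lost without fibre replicate 2 or 3 (limma camera adjusted p = 0.0882 and 0.112). Their mean log2 level was 7.19, 4.14 and 4.01 in fibre replicates 1, 2 and 3, against 7.17 to 7.54 in B2-3 progenitors.

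In this comparison 2522 of 17146 genes were called, 1030 higher and 1492 lower, the groups did not overlap in 52.2% of tested genes (10% by chance), and the median change of all genes was -0.23. Median-of-ratios scaling gave 1287 higher and 905 lower, and quantile normalization 1237 and 1043. Without B2-3 replicate 3 the count was 1491, 788 higher and 703 lower, and without fibre replicate 2 there were 856 higher and 917 lower.

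Alveolar differentiation was compared with the fibre-expanded progenitors it started from. SFTPB rose by 4.31 ± 0.64 (limma adjusted p = 0.00177), to 10166 ± 1751 TPM from 656 ± 506, and the alveolar type 1 gene HOPX rose by 6.22 ± 0.51 (limma adjusted p = 2.33e-05). Cell cycle genes fell across their list, with MKI67 down by 1.90 ± 0.37 (limma adjusted p = 0.00796). NKX2-1 stood at 129 ± 7.59 against 134 ± 16.4 TPM (limma adjusted p = 0.936).

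Alveolar type 2 genes were higher in 9 of 20 (12 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 2.08e-10, and adjusted p = 0.115 with an estimated correlation). The phosphate carrier SLC34A2 rose by 4.62 ± 0.59, PGC by 3.77 ± 0.61 and SFTA2 by 2.47 ± 0.47. ABCA3 rose by 1.55 ± 0.34, a call lost without fibre replicate 3 (limma adjusted p = 0.0696, range 0.00456 to 0.0696 over all settings). SFTPC was at 3145, 4709 and 27291 TPM in alveolar-differentiated libraries against 2236, 2142 and 1119.6 (2.08 ± 0.60, limma adjusted p = 0.0488). With the replicate number as a block, the adjusted p for SFTPC was 0.0602 and the call was lost, as it was without any 1 of 10 of the 12 culture libraries, the exceptions being alveolar replicate 1 and airway replicate 1 (range 0.0131 to 0.183 over all settings). Alveolar type 1 genes were higher in 10 of 18 (12 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 2.51e-13, and adjusted p = 0.115 with an estimated correlation). SPOCK2 rose by 5.13 ± 0.57, EMP2 by 3.45 ± 0.25 and AGER, a receptor abundant on alveolar type 1 cells, by 2.93 ± 0.58. PDPN did not pass, at 8.86 ± 3.03 against 4.15 ± 1.21 TPM.

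Airway secretory genes also rose, in 5 of 12, with 1 lower (7 higher and 2 lower adjusted over the list alone, limma camera adjusted p = 1.68e-05, and adjusted p = 0.0787 with an estimated correlation). SLPI rose by 8.85 ± 0.35 and SCGB3A2 by 6.25 ± 0.41, to 222 ± 121 TPM. Among the strongest changes were the keratins of stratified epithelium KRT13 and KRT4, at 6.29 ± 0.79 and 5.74 ± 0.58, with the neuropeptide gene NMU at 7.42 ± 0.55 and the chemokine CXCL13 at 6.48 ± 0.46. ALPP, a placental alkaline phosphatase, stood at 119, 41.8 and 75.2 TPM and was listed at 0 in every fibre library. Transitional genes rose in 3 of 12 (4 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 0.00175, and adjusted p = 0.249 with an estimated correlation). KRT7, a keratin of simple epithelia, rose by 3.28 ± 0.54. Of the neuroendocrine list 3 of 13 rose (4 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 0.000701, and adjusted p = 0.249 with an estimated correlation). The peptide gene GRP rose by 3.44 ± 0.46.

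Glucocorticoid response genes were higher in 5 of 10 (6 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 3.94e-08, and adjusted p = 0.0814 with an estimated correlation). ZBTB16, KLF9 and FKBP5 rose by 3.92 ± 0.50, 2.41 ± 0.26 and 2.29 ± 0.38. Sodium channel subunits SCNN1A and SCNN1B rose by 3.99 ± 0.40 and 3.78 ± 0.38, within a fluid transport list with 3 of 10 higher (4 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 0.000837, and adjusted p = 0.139 with an estimated correlation). Genes of the endothelial list were higher in 2 of 5 (limma camera adjusted p = 0.0125, and adjusted p = 0.115 with an estimated correlation). The tight junction gene CLDN5 rose by 2.86 ± 0.44, and without the filter on low TPM the list was not called (limma camera adjusted p = 0.0970). MHC class I and interferon response genes had 1 of 15 higher (limma camera adjusted p = 0.00175, and adjusted p = 0.256 with an estimated correlation).

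The proliferation list had 23 of 26 members lower (0 higher and 24 lower adjusted over the list alone, limma camera adjusted p = 8.49e-17, and adjusted p = 0.139 with an estimated correlation). RRM2, of nucleotide synthesis, changed by -2.51 ± 0.39, cyclin A2 gene CCNA2 by -2.37 ± 0.34 and BIRC5 by -2.25 ± 0.41. Distal tip progenitor genes were lower in 6 of 16 (0 higher and 8 lower adjusted over the list alone, limma camera adjusted p = 1.62e-06, and adjusted p = 0.0569 with an estimated correlation), among them ETV5 (-3.32 ± 0.43), ETV4 (-2.75 ± 0.45) and HMGA2 (-2.14 ± 0.42). WNT targets were lower in 4 of 11 (0 higher and 6 lower adjusted over the list alone, limma camera adjusted p = 0.000119, and adjusted p = 0.163 with an estimated correlation). LGR5 changed by -3.79 ± 0.46. Sterol and fatty acid synthesis genes were lower in 9 of 17 (limma camera adjusted p = 1.23e-06, and adjusted p = 0.211 with an estimated correlation). SQLE, the squalene epoxidase gene, changed by -1.72 ± 0.33. Genes of the non-lung endoderm list were lower in 6 of 15 (0 higher and 7 lower adjusted over the list alone, limma camera adjusted p = 0.0128, and adjusted p = 0.139 with an estimated correlation). HNF4A, a regulator of liver and gut, changed by -1.83 ± 0.35, and the list call was lost without fibre replicate 2 or alveolar replicate 1 (limma camera adjusted p = 0.0679 and 0.0579). The basal, mesenchymal, multiciliated and immediate early and dissociation stress lists were called at the preset correlation (limma camera adjusted p = 0.0245, 0.0226, 0.0240 and 0.0125). They had 3, 0, 2 and 0 members higher and 1, 0, 1 and 0 lower, and each was lost without alveolar replicate 1 (limma camera adjusted p = 0.0955, 0.599, 0.0961 and 0.451). Median-of-ratios scaling ended the calls of the first 3 (limma camera adjusted p = 0.103, 0.103 and 0.112). Without fibre replicate 2 the basal, mesenchymal and immediate early lists were lost too (limma camera adjusted p = 0.0679, 0.0679 and 0.125), and without fibre replicate 3 the immediate early list (limma camera adjusted p = 0.142). Adjusted over the list alone, the basal list had 5 higher and 1 lower. With an estimated correlation the limma camera adjusted p of these 4 was 0.286, 0.423, 0.649 and 0.512. The mean log2 level of the immediate early list was 7.80, 5.06 and 4.81 in alveolar replicates 1, 2 and 3 and 7.19, 4.14 and 4.01 in fibre replicates 1, 2 and 3, so each was above the fibre replicate of its number, and with the replicate number as a block the list was called (limma camera adjusted p = 0.00414).

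Alveolar differentiation changed 1187 of 17146 genes, 461 higher and 726 lower, with no overlap in 32.0% of tested genes (10% by chance) and a median change of all genes of -0.15. Median-of-ratios scaling gave 702 higher and 607 lower, and quantile normalization 607 and 620. Without fibre replicate 1, 2 or 3 there were 319 higher and 372 lower, 323 and 476, or 236 and 284. Without alveolar replicate 3 there were 421 higher and 378 lower, with a median change of -0.01.

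Airway differentiation, from the same fibre-expanded progenitors, was marked by cilia. FOXJ1 rose by 6.13 ± 0.48 (limma adjusted p = 2.22e-06), from 1.57 ± 0.441 to 208 ± 150.2 TPM, and the cilia genes SNTN and ZMYND10 rose by 8.43 ± 0.52 and 8.83 ± 0.69. SFTPC fell by 10.35 ± 0.60 (limma adjusted p = 4.60e-07), to 0, 0.619 and 0.502 TPM in the 3 libraries. SCGB3A2 rose by 7.29 ± 0.41, while SCGB1A1, the secretoglobin of club cells, was listed at 0 in all airway-differentiated libraries.

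Of the multiciliated list 22 of 23 members rose and 0 fell (23 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 1.52e-19, and adjusted p = 0.251 with an estimated correlation), among them CAPS (6.94 ± 0.42) and SPAG6 (7.43 ± 0.50). TEKT1 and C20orf85, at 90.0, 122 and 406 and 338, 366 and 1151 TPM in airway-differentiated libraries, were listed at 0 in every fibre library. Alveolar type 1 genes were higher in 14 of 18 (limma camera adjusted p = 2.96e-07, and adjusted p = 0.262 with an estimated correlation). SPOCK2 rose by 4.87 ± 0.57, HOPX by 4.26 ± 0.51, SCEL by 4.18 ± 0.65, CAV1 by 3.89 ± 0.42, AGER by 3.78 ± 0.58 and PDPN by 3.62 ± 0.50. Many of these genes are also expressed by airway basal and other epithelial cells. Airway secretory genes were higher in 5 and lower in 2 of 12 (5 higher and 3 lower adjusted over the list alone, limma camera adjusted p = 0.152). LCN2, an antimicrobial lipocalin, rose by 6.14 ± 0.48 and SLPI by 6.14 ± 0.35, while SPDEF, a regulator of goblet cells, was lower (-3.19 ± 0.52). Genes of the alveolar type 2 list fell in 8 and rose in 1 of 20 (3 higher and 9 lower adjusted over the list alone, limma camera adjusted p = 0.00570, and adjusted p = 0.421 with an estimated correlation). SFTPA2 changed by -4.77 ± 0.81 and PGC by -5.23 ± 0.61. That list call was lost without airway replicate 1 (limma camera adjusted p = 0.0830). SFTPB was at 213 ± 218 against 656 ± 506 TPM and did not pass. Basal genes were higher in 3 of 9 (limma camera adjusted p = 0.191). KRT17 rose by 3.80 ± 0.70 and NGFR, a neurotrophin receptor of basal cells, by 2.31 ± 0.42, and TP63 was at 0.516 ± 0.323 TPM.

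The distal tip progenitor list had 11 of 16 members lower (0 higher and 12 lower adjusted over the list alone, limma camera adjusted p = 1.51e-08, and adjusted p = 0.0201 with an estimated correlation). GATA6, an endoderm transcription factor, changed by -2.90 ± 0.29, ETV5 by -2.77 ± 0.43 and SHH by -2.66 ± 0.39. CPM fell by 2.34 ± 0.24. NKX2-1 fell by 1.23 ± 0.27 (limma adjusted p = 0.00435), to 60.3 ± 25.2 TPM, and its change was -0.86 without airway replicate 1, under the limit. The non-lung endoderm list fell in 8 and rose in 1 of 15 (1 higher and 11 lower adjusted over the list alone, limma camera adjusted p = 5.27e-07, and adjusted p = 0.0208 with an estimated correlation). APOA2 changed by -5.65 ± 0.67, FABP1 by -5.54 ± 0.40 and LGALS4 by -5.10 ± 0.57. Proliferation genes fell in 18 of 26 (0 higher and 20 lower adjusted over the list alone, limma camera adjusted p = 2.52e-11, and adjusted p = 0.271 with an estimated correlation). MKI67 changed by -2.03 ± 0.37. WNT targets fell in 8 of 11 (limma camera adjusted p = 2.68e-05, and adjusted p = 0.251 with an estimated correlation). LGR5 changed by -4.29 ± 0.46 and the feedback inhibitor AXIN2 by -2.30 ± 0.39. Sterol and fatty acid synthesis genes fell in 6 of 17 (0 higher and 8 lower adjusted over the list alone, limma camera adjusted p = 5.18e-06, and adjusted p = 0.281 with an estimated correlation), and the last enzyme of cholesterol synthesis, DHCR7, changed by -1.83 ± 0.31.

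Stromal genes rose after airway differentiation as well. Across airway replicates 1, 2 and 3 the mesenchymal list summed to 1554, 797 and 740 TPM. The multiciliated list summed to 4007, 5445 and 15750 TPM, the opposite order. The mesenchymal list had 11 of 13 members higher and 1 lower (limma camera adjusted p = 0.00118, and adjusted p = 0.334 with an estimated correlation). THY1 rose by 4.82 ± 1.17 and POSTN, a matrix protein gene, by 2.95 ± 0.75. Endothelial genes were higher in 3 of 5 (limma camera adjusted p = 0.106), and KDR, a VEGF receptor, rose by 2.98 ± 0.41. Neuroendocrine genes were higher in 6 and lower in 1 of 13 (limma camera adjusted p = 0.00357, and adjusted p = 0.348 with an estimated correlation). The granin gene SCG2 rose by 2.77 ± 0.49 and CALCA, of calcitonin gene-related peptide, by 2.43 ± 0.43. MHC class I and interferon response genes rose in 11 of 15 (limma camera adjusted p = 1.86e-06, and adjusted p = 0.251 with an estimated correlation). IFIT1 rose by 3.05 ± 0.40 and IFI6 by 2.94 ± 0.29, and HLA-DRA of the MHC class II list rose by 3.44 ± 0.40. Glucocorticoid response genes were higher in 6 of 10 (limma camera adjusted p = 0.00118, and adjusted p = 0.262 with an estimated correlation), led by the metallothionein MT2A (6.63 ± 0.78). The NOTCH target HES1 fell by 2.50 ± 0.43 in a list with 1 of 10 higher and 3 lower (limma camera adjusted p = 0.222). ANKRD37 and EGLN3, targets of hypoxia-inducible factor, rose by 4.77 ± 0.57 and 3.03 ± 0.53, the 2 of 16 glycolysis and hypoxia response genes called (limma camera adjusted p = 0.376). The fluid transport list had 3 higher and 3 lower of 10 (limma camera adjusted p = 0.512). AQP4 was higher (3.38 ± 0.76) and CLDN18 lower (-2.76 ± 0.52).

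Airway-differentiated cells differed from fibre-expanded progenitors in 3500 of 17146 genes, 2286 higher and 1214 lower, with no overlap in 42.8% of tested genes (10% by chance) and a median change of all genes of 0.02. Median-of-ratios scaling gave 2369 higher and 1228 lower, and quantile normalization 1932 and 1891.

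**Figure D2:**
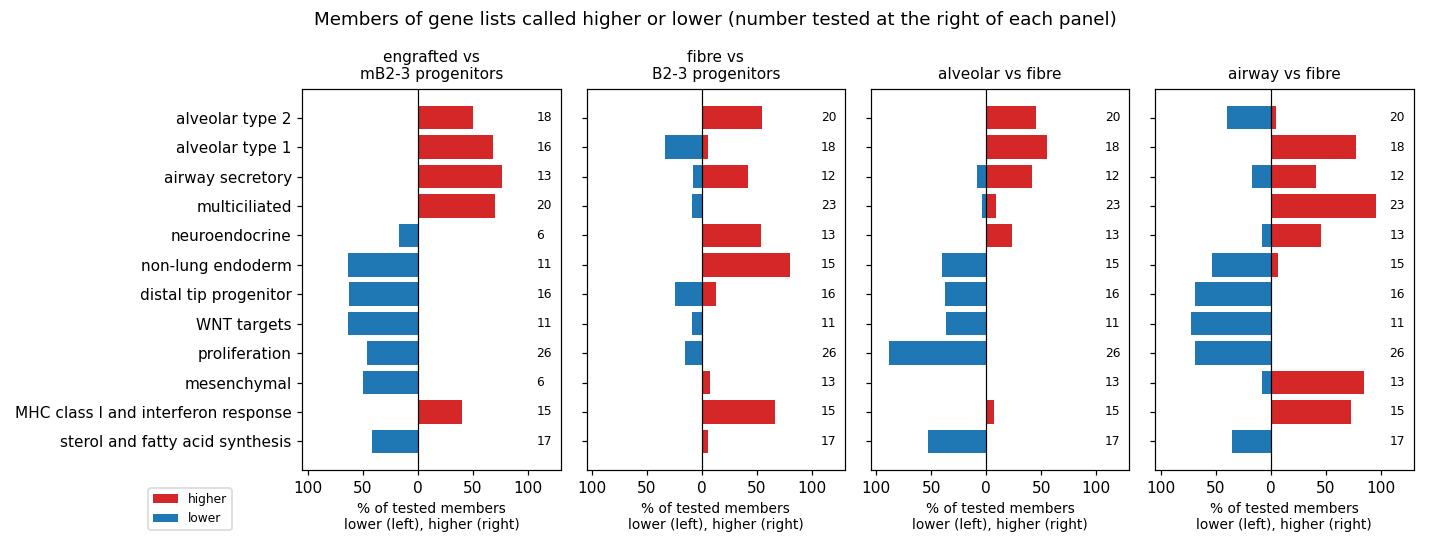
Bars show the percentage of tested members of 12 gene lists called higher (red, to the right) or lower (blue, to the left) in 4 comparisons, with the number of members tested at the right of each panel. The multiciliated list had 22 of 23 members higher in airway-differentiated cells, and the non-lung endoderm list 12 of 15 higher in fibre-expanded progenitors.

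A direct comparison of alveolar-differentiated with airway-differentiated cells tested how the differentiations differed. SFTPC was higher in alveolar-differentiated cells by 12.43 ± 0.60 (limma adjusted p = 3.94e-07) and SFTPB by 6.03 ± 0.64. FOXJ1 was lower (-5.27 ± 0.48, limma adjusted p = 9.16e-06), as was SNTN (-7.79 ± 0.52). Of the alveolar type 2 list 13 of 20 members were higher and 1 lower (14 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 2.58e-15, and adjusted p = 0.135 with an estimated correlation), and of the multiciliated list all 23 tested members were lower (limma camera adjusted p = 8.47e-21, and adjusted p = 0.141 with an estimated correlation). ABCA3 was higher by 1.87 ± 0.34 and SFTPA1 by 9.76 ± 0.76.

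Alveolar type 1 genes showed 1 higher and 1 lower of 18 (limma camera adjusted p = 0.957). AGER was at 37.9 ± 12.3 TPM in alveolar-differentiated and 93.6 ± 90.9 in airway-differentiated cells and did not pass, while PDPN was lower (-2.71 ± 0.50). Airway secretory genes moved apart, with MSMB and SLPI higher by 3.59 ± 0.41 and 2.71 ± 0.35 and LCN2 lower (-5.69 ± 0.48), and the list had 2 higher and 1 lower of 12 (limma camera adjusted p = 0.0883). SCGB3A2 was at 222 ± 121 against 441 ± 175 TPM and did not pass. The non-lung endoderm list was higher in 9 of 15 (limma camera adjusted p = 6.01e-07, and adjusted p = 0.0385 with an estimated correlation). APOA2 was higher by 3.70 ± 0.67, FABP1 by 3.54 ± 0.40 and LGALS4 by 2.57 ± 0.57. GUCA2B, an intestinal peptide, was higher by 4.64 ± 0.44. The distal tip progenitor list was higher in 5 of 16 (5 higher and 1 lower adjusted over the list alone, limma camera adjusted p = 0.00870, and adjusted p = 0.141 with an estimated correlation). The tip regulator ID2 was higher by 1.90 ± 0.25 and CPM by 1.77 ± 0.24, and this list was not called under quantile normalization (limma camera adjusted p = 0.0553).

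Fluid transport genes were higher in 3 of 10 (4 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 6.07e-05, and adjusted p = 0.141 with an estimated correlation). The growth factor AREG was higher by 2.94 ± 0.52. MHC class I and interferon response genes were lower in 9 of 15 (limma camera adjusted p = 0.00117, and adjusted p = 0.454 with an estimated correlation). Interferon-induced IFI6 (-2.61 ± 0.29), IFIT1 (-2.56 ± 0.40) and MX1 (-1.77 ± 0.37) were lower. The MHC class II gene HLA-DRA (-3.03 ± 0.40), the VEGF receptor KDR (-2.90 ± 0.41) and the neurotrophin receptor NGFR (-2.35 ± 0.42) were lower as well. The fatty acid synthase FASN was higher by 1.62 ± 0.26, HES1 by 2.22 ± 0.43, and ANKRD37 was lower (-3.17 ± 0.57). MKI67 was at 3.34, 1.05 and 1.61 against 2.69, 0.698 and 1.83 TPM (limma adjusted p = 0.854).

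Between the differentiated groups 2622 of 17146 genes were called, 593 higher and 2029 lower in alveolar-differentiated cells, with no overlap in 28.5% of tested genes (10% by chance) and a median change of -0.17. Quantile normalization gave 1260 higher and 1487 lower. A fit of these 2 groups alone called 1709 genes.

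Set against the B2-3 progenitors before expansion, alveolar-differentiated cells combined both steps of the culture. SFTPB was higher by 13.06 ± 0.64 (limma adjusted p = 9.05e-08), SFTPC by 12.53 ± 0.60 and ABCA3 by 2.92 ± 0.34. The cartilage collagen gene COL2A1 was lower (-5.72 ± 0.47, limma adjusted p = 4.61e-06), as were the proto-oncogene MYCN (-4.72 ± 0.48) and SHH (-2.77 ± 0.39). Alveolar type 2 genes were higher in 13 of 20 (14 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 1.57e-15, and adjusted p = 0.0555 with an estimated correlation) and alveolar type 1 genes in 10, with 3 lower, of 18 (limma camera adjusted p = 5.13e-05, and adjusted p = 0.251 with an estimated correlation). HOPX rose by 3.82 ± 0.51 and PDPN fell by 2.53 ± 0.50, while AGER stood at 37.9 ± 12.3 against 20.6 ± 9.46 TPM.

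Airway secretory genes rose in 10 of 12 (12 higher and 0 lower adjusted over the list alone, limma camera adjusted p = 2.72e-12, and adjusted p = 0.00923 with an estimated correlation). AGR2, a mucin-folding enzyme gene, rose by 6.79 ± 0.40, and SLPI was at 961, 321 and 379.7 TPM and listed at 0 in every B2-3 library. Genes of the non-lung endoderm list were higher in 11 and lower in 1 of 15 (limma camera adjusted p = 1.00e-08, and adjusted p = 0.0102 with an estimated correlation). APOA2 rose by 6.76 ± 0.67. The adhesion gene CEACAM5 rose by 8.30 ± 0.39. Neuroendocrine genes were higher in 9 of 13 (limma camera adjusted p = 2.80e-09, and adjusted p = 0.0662 with an estimated correlation). CHGA rose by 6.88 ± 0.58. MHC class I and interferon response genes were higher in 11 of 15 (limma camera adjusted p = 2.83e-09, and adjusted p = 0.0632 with an estimated correlation), among them OAS1 (6.11 ± 0.40) and B2M (2.78 ± 0.24), the light chain of MHC class I. Transitional genes rose in 7 of 12 (limma camera adjusted p = 1.04e-05, and adjusted p = 0.114 with an estimated correlation). LGALS3 rose by 4.25 ± 0.24. Fluid transport genes were higher in 6 and lower in 1 of 10 (limma camera adjusted p = 9.23e-07, and adjusted p = 0.0555 with an estimated correlation). SCNN1A rose by 4.17 ± 0.40. Glucocorticoid response genes were higher in 6 of 10 (limma camera adjusted p = 0.000194, and adjusted p = 0.114 with an estimated correlation), among them FKBP5 (2.62 ± 0.38), a chaperone that binds the glucocorticoid receptor. Macrophage and leukocyte genes were higher in 2 of 4 (limma camera adjusted p = 0.00389, and adjusted p = 0.0555 with an estimated correlation).

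Distal tip progenitor genes were lower in 12 of 16 (limma camera adjusted p = 0.000590, and adjusted p = 0.0555 with an estimated correlation). HMGA2, a chromatin protein of fetal cells, changed by -3.15 ± 0.42, and CPM was lower (-1.38 ± 0.24), a call lost under median-of-ratios scaling (-0.91). Proliferation genes were lower in 24 and higher in 1 of 26 (limma camera adjusted p = 2.80e-09, and adjusted p = 0.251 with an estimated correlation). The mitotic kinase gene AURKB changed by -3.65 ± 0.46 and MKI67 by -2.94 ± 0.37. WNT targets were lower in 10 and higher in 1 of 11 (limma camera adjusted p = 0.00224, and adjusted p = 0.251 with an estimated correlation). SP5, a transcription factor switched on by WNT, changed by -3.24 ± 0.52. CCN2 (-4.92 ± 0.98) and ADM (-3.86 ± 0.54) were lower too. The basal, mesenchymal and endothelial lists were called at the preset correlation (limma camera adjusted p = 0.0369, 0.0344 and 0.0275) with 3, 1 and 2 members higher and 2, 0 and 0 lower, but not with an estimated correlation (limma camera adjusted p = 0.316, 0.486 and 0.104). Adjusted over the list alone, the basal list had 4 higher and 2 lower and the endothelial list 3 and 0. All 3 were lost under median-of-ratios scaling (limma camera adjusted p = 0.222, 0.223 and 0.0856), the endothelial list also without alveolar replicate 3 (limma camera adjusted p = 0.0532). The basal and mesenchymal lists were also lost without B2-3 replicate 3 (limma camera adjusted p = 0.0719 and 0.0719) and alveolar replicate 1 (limma camera adjusted p = 0.0766 and 0.440).

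Over the whole culture course 4960 of 17146 genes were called, 1413 higher and 3547 lower, with no overlap in 55.9% of tested genes (10% by chance) and a median change of -0.37. Median-of-ratios scaling gave 2306 higher and 1905 lower, and quantile normalization 1934 and 2100.

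The transplant comparison and this culture comparison were then set side by side for the 13940 genes tested in both, without a test across the separately normalized tables, which share no library. SFTPB, SFTPC, SCGB3A2, SLPI, KRT15 and PSMB8 were called higher in both, and COL2A1, SHH, HMGA2, SP5 and ADM lower in both. Genes called higher in both numbered 321, where independent lists of these sizes would share 58.1, and genes called lower in both numbered 1180, against 505. Median-of-ratios scaling gave 527 higher and 566 lower in both, against 142 and 158 for independent lists, and quantile normalization 534 and 580, against 133 and 165. Another 25 genes were higher in engrafted and lower in alveolar-differentiated cells, against 192 for independent lists, and 40 were lower and higher, against 152. Across genes the changes correlated at a Pearson r of 0.553 and a Spearman rho of 0.512, where genes are not independent replicates. SCGB3A2 was higher by 12.88 ± 0.51 in engrafted and by 4.91 ± 0.41 in alveolar-differentiated cells. SFTPC was higher by 7.31 ± 0.45 and 12.53 ± 0.60, each against its own progenitors, with the difference not tested. Without mB2-3 replicate 1, 2 or 3 the shared calls fell from 1501 to 233, 328 or 275, with 138, 176 or 156 higher and 95, 152 or 119 lower in both. Without engrafted replicate 1 or 3, 148 or 175 were higher and 884 or 1130 lower in both.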

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

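The tests of the sources of the airway and alveolar lists in engrafted cells and of the non-lung endoderm list after fibre expansion were chosen only after the result was seen, while the comparisons and the splits of the libraries were planned. The alveolar type 2 list was called higher in alveolar-differentiated and lower in airway-differentiated cells, each against fibre-expanded progenitors, at the preset correlation. Those calls were lost with an estimated correlation (limma camera adjusted p = 0.115 and 0.421), and the airway one also without airway replicate 1 (limma camera adjusted p = 0.0830). Compared directly, the median member differed by a log2 of 1.85, and SFTPC by 12.43. The non-lung endoderm list had a mean change of -2.20 in engrafted cells against mB2-3 progenitors and of 3.07 in alveolar-differentiated cells against B2-3 progenitors over all 16 fixed members, and of -3.10 and 3.27 over the 11 and 15 tested ones. These come from separately normalized tables, and the difference was not tested.

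Each comparison was repeated over all 10 splits of its 6 libraries into 3 and 3. In every comparison 1 split, the real one itself, reached the real count of genes. With 10 splits the smallest possible share is 1 of 10. Every other split mixes libraries of both groups, so their difference enters the spread and few calls are possible. The counts below therefore cannot decide whether chance made the groups differ. Engrafted cells against mB2-3 progenitors gave 3145 genes in the real split and 6 in the highest other. Fibre-expanded against B2-3 progenitors gave 2522 and 2. Alveolar and airway differentiation against fibre-expanded progenitors gave 1187 and 0, and 3500 and 0. The differentiated groups against each other gave 2622 and 3, and alveolar-differentiated cells against B2-3 progenitors 4960 and 0. Among the splits of the alveolar comparison that parted every replicate pair, the highest other count was also 0.

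List calls at the preset correlation behaved otherwise. The real split and the highest other called 17 and 13 lists in engrafted cells, 10 and 10 after fibre expansion, and 18 and 15 after alveolar differentiation. They called 12 and 13 after airway differentiation, 6 and 11 between the differentiated groups, and 16 and 17 in alveolar-differentiated cells against B2-3 progenitors. The number of splits with at least as many lists, the real one included, was 1, 3, 1, 2, 9 and 3 in that order. Every other split keeps part of the group difference, which can still rank the genes of a list. These counts therefore give no rate of false list calls.

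Airway and alveolar lists rose together in engrafted cells, which human cells of several lung fates would give, and which RNA of the mouse lung or 1 sparse library might also give. RNA of the whole mouse lung would bring endothelial, mesenchymal and leukocyte genes, whose summed TPM was at most 0.375% of that of the 4 airway and alveolar lists in any engrafted library (173, 125 and 198 TPM against 84967, 89751 and 52621, of which SCGB3A2 made up 56798, 66639 and 26936). The endothelial, mesenchymal and leukocyte genes summed to 179, 243 and 140 TPM in mB2-3 progenitors. This argues against whole-lung RNA as the source only if mouse reads of those cells were counted like those of epithelium. How mouse reads were handled is not known, so whole-lung RNA is not excluded. A small part from host leukocytes is not excluded either, since their list summed to 91.3, 115 and 79.9 TPM, with CTSS at 88.9, 109 and 75.3, against 9.57, 8.68 and 10.3 in progenitors. Without a host, the list summed to 73.5, 162 and 104 TPM in fibre-expanded and 100, 125 and 172 in airway-differentiated cells, normalized separately. It summed to 112, 112 and 58.8 in alveolar-differentiated cells and 8.26, 9.93 and 8.73 in B2-3 progenitors. Against B2-3 progenitors the sum thus rose in culture without a host, so a rise of the list does not by itself point to host cells. Of its 3 members tested in engrafted cells, CD68 and CTSS were called higher and FCER1G lower. Of 4 genes without a mouse ortholog, CEACAM5, CEACAM6, S100P and CXCL8, 4 were called higher, which a change in human cells would give. Mouse reads of other genes aligned to them are not excluded, since the handling of mouse reads is not known. These 4 genes belong to none of the 4 lists, so their rise does not show the source of the lists. Reads of mouse epithelium aligned to human genes are not excluded. Without engrafted replicate 2, the sparse library, 4 of the 4 lists were still called at the preset correlation, with 10 of 17 alveolar type 2, 9 of 13 alveolar type 1 and 14 of 15 multiciliated members higher, so that library alone is excluded as the source. 

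In that refit the filter drops genes at 0 in progenitors, so 5 of 13 airway secretory members were tested and 3 were higher. With all libraries, the alveolar type 2 and type 1 calls were lost with an estimated correlation (limma camera adjusted p = 0.166 and 0.151).

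The non-lung endoderm list rose after fibre expansion, which cells of gut or liver fate in the fibres would give, and which 1 library, the scaling between libraries or the loss of an earlier sorting step might also give. The list was called higher in 12 of 12 refits without 1 culture library, so 1 library is excluded. At least 14 of its members were called higher under median-of-ratios scaling or quantile normalization, against 12 with TPM as deposited. The rise therefore did not depend on the choice among these scalings. Median-of-ratios factors were 1.18 to 1.22 in B2-3 and 0.978 to 1.02 in fibre libraries. Dividing by them could only raise fibre levels relative to B2-3, so the added calls are no further evidence. The column headers of the B2-3 libraries read MACS, a usual short form of magnetic cell sorting, and those of the fibre libraries do not. Sorting was not tested and remains open.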

How the results depend on the processing

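Calls were recounted under other settings, and the cause of these differences was not tested. In engrafted cells 2093 genes were called among those with 5 TPM or more in at least 3 libraries and 2766 with a replicate block, and refits without 1 library gave 471 to 4362. ABCA3 in engrafted cells changed direction, from -0.72 without engrafted replicate 3 to 1.28 without engrafted replicate 2. For fibre expansion a pseudocount of 5 gave 1339 genes, the block 2523 and refits without 1 library 1491 to 2726. Alveolar differentiation gave 727 with a pseudocount of 5, 700 without the filter on low TPM, 1144 with the block (1067 shared with the fit without it), and 520 to 1390 without 1 library. Airway differentiation gave 2148 with a pseudocount of 5, 3550 with the block and 2750 to 3599 without 1 library. Between the differentiated groups a pseudocount of 5 gave 1672, a fit of the 2 groups alone 1709, the block 2690 and refits without 1 library 1893 to 3057. Alveolar-differentiated cells against B2-3 progenitors gave 2646 with a pseudocount of 5, 4987 with the block and 3995 to 5475 without 1 library. List calls numbered 10 with an estimated correlation, 81 with the block, 76 to 83 under the other settings and 73 to 82 without 1 library. Calls shared by engrafted and alveolar-differentiated cells numbered 1085 to 1541 under other settings and 233 to 1977 without 1 library. Settings added after the data were seen changed little. Transplant libraries rescaled to an equal sum gave 3208 genes, and the culture table limited to symbols of the transplant table gave 4845 for alveolar-differentiated cells against B2-3 progenitors.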

Other observations

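The genes in this part were picked after the values were seen, and the tests on POU5F1 were chosen only after its result was seen. In alveolar-differentiated cells ASNS, which makes asparagine, was higher than in fibre-expanded progenitors by 2.46 ± 0.15 (limma adjusted p = 4.02e-06), PSAT1, of serine synthesis, by 2.82 ± 0.19, and the stress response gene CHAC1 by 3.07 ± 0.37. DDIT4, an inhibitor of mTORC1 and a glucocorticoid target, was higher by 2.47 ± 0.33. In airway-differentiated cells GHRL, the gene of the hormone ghrelin, rose by 7.28 ± 0.60 (limma adjusted p = 2.97e-06), at 518, 3080.1 and 4708 TPM against 15.1, 11.8 and 8.65.

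POU5F1, the pluripotency factor OCT4, stood at 2486, 2123 and 728 TPM in airway-differentiated libraries, against 82.6, 0 and 1.85 in fibre-expanded progenitors, 946, 0.818 and 1.07 in alveolar-differentiated cells and 0, 0.253 and 1.23 in B2-3 progenitors. Its rise of 7.98 ± 2.01 (limma adjusted p = 0.0107) after airway differentiation was lost without fibre replicate 2 (limma adjusted p = 0.0508).

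Leftover iPS cells, reads of POU5F1 pseudogenes or reprogramming transgenes still carried by the line might each give the POU5F1 levels. The other 8 pluripotency genes summed to at most 2.47% of POU5F1 in any airway-differentiated library, so leftover iPS cells are excluded as the source of its level. Of the pluripotency list 4 of 7 members, POU5F1, DPPA4, TDGF1 and L1TD1, were nonetheless called higher and 1, ZFP42, lower (limma camera adjusted p = 0.377), so a small share of such cells is not excluded. Pseudogene copies summed to at most 7.60% of POU5F1. Reads of the copies could have been counted at POU5F1 itself, so this cannot exclude them as the source. KLF4, MYC and SOX2, the other reprogramming factors, were highest in the library highest in POU5F1 in 9 of 9 places over the fibre, alveolar and airway groups, where chance gives 3. That library was replicate 1 in each of these groups, so the 9 places are not independent and their number cannot be weighed against chance. The immediate early list was also highest in that library in 3 of 3 groups, and KLF4 and MYC respond to the same stimuli. That does not cover SOX2, which was highest there in 3 of 3 groups too. Transgenes therefore remain open.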
